A study of Mus musculus with 14 samples.

How the data were processed

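RNA from 14 osteoblast cultures, each grown from the marrow of 1 UM-HET3 mouse, was sequenced from stranded total RNA libraries with ribosomal RNA depleted. The deposited values are counts, whole numbers of reads per gene symbol, in 1 table for the 6 female libraries and 1 for the 8 male libraries. The submitters' processing notes name the GRCm38 genome and the tools HISAT2 2.1.0.13, HTSeq and DESeq2, with no role or order and no gene annotation. The deposited counts are not normalized: the library totals differ and no value is fractional. Groups were taken from the sample titles. A second sheet with the male table, whose name says not to use it, held 3 columns that repeat deposited male libraries and 5 columns that match no sample, and none of these was used in any step.

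Each table had 35976 gene names. In each, 4 entries with dates in place of symbols and a repeated name were left out, at most 0.019% of any library, and 23 other entries with a date as their name were kept. Total counts ran from 4532751 to 10617990 per library, which leaves genes under about 1 CPM with few reads. Replicate libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 7.76 to 30.5 over genes with at least 20 counts, so tests used the spread between mice. Coordinates came from the RefSeq gene table of GRCm38.

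Comparisons were made in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr, a robust quasi-likelihood fit, and Benjamini-Hochberg adjustment with a threshold of 0.05, two-sided. Female and male diet effects were fitted apart. The difference between sexes and the comparison of the sexes on control diet came from 1 fit of all 14 libraries and the genes in both tables. The SE of a log2 fold change is its size over the square root of the F statistic. CPM values given per group are means with SD over libraries, scaled with TMM over all libraries.

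There were 30 gene lists fixed before the data were examined, covering bone, fat, stromal, immune, vascular, muscle and cartilage cells, metabolism, signaling and stress. They were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2) where at least 5 members were tested, then with an estimated correlation and with fry. Adjustment was over the lists tested. No list call at the preset correlation held with an estimated correlation, in any of the 3 diet comparisons. The lists of erythroid and skeletal muscle genes had fewer than 5 tested members in every comparison, those of lymphocytes and endothelium in each sex, and that of granulocytes and mast cells in females (3), and were not tested there. A list count given "over the list alone" adjusts each gene's p within its list. The lists share some genes, and 3 more lists were chosen after the leading genes had been seen.

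The correlation of the osteoblast and adipocyte scores was tested with 100000 resamples. Library measures (total counts, genes with reads, the TMM factor, shares of counts and mean log2 CPM of 5 lists) were compared with exact two-sided permutation tests within each sex, 28 tests adjusted together. The difference between sexes in 5 scores was tested by exact permutation of diet labels within sex, added after the list results were seen.

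The genes to name were fixed by a rule written before the data were examined. It took, in each sex, up to 10 genes each way with the largest change among those that passed, had a mean log2 CPM above 0, a plain symbol and groups that did not overlap, filled up to 5 by the smallest p where fewer passed. It added a set of 15 bone, fat, glucose and drug target genes whatever their result, and up to 4 members with the smallest p from each list described. For the 2 other comparisons it took 5 each way, and for the sexes on control diet also Xist and 4 Y-linked genes. For the difference between sexes the condition on overlap was not applied. How many members of each list were named, and which lists that did not pass were described, was chosen after the values were seen. Genes of the 3 added lists were chosen after their values were seen.

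Alternatives fixed beforehand were RLE and upper quartile normalization, DESeq2 1.42.0, limma-voom with quality weights, no filter beyond a total above 0, a filter of CPM above 1, the replicate number as a block, a fit of all 4 groups, no robust dispersion, an absolute log2 fold change above 1, and leaving out each library in turn. Added after the data were seen were libraries thinned to the smallest female total, the macrophage score as a covariate, and a test on held-out males. In it, as many genes each way as had passed were chosen by p in 3 against 3 male libraries and measured as the log2 CPM difference of the 2 libraries left out, for all 16 pairs. It replaced a comparison of the genes that passed, which had been chosen in the same libraries. For the difference between sexes, 60 splits of the libraries were drawn to limit the running time.

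The pipeline was tested on simulated data. With groups of the female sizes, edgeR recovered 1.49%, 38.8% and 75.8% of genes changed 1.5-fold, 2-fold and 4-fold. With the male sizes it recovered 14.9%, 47.8% and 90.9%, and for the difference between sexes 1.49%, 20.9% and 60.6%. False calls were 16 of 93, 9 of 111 and 5 of 60, above the nominal 1 in 20, and with no change simulated edgeR called 3, 0 and 0 genes. A list shifted by -0.5 (log2) was called in each comparison, with 0 other lists. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. In the female libraries the estimated correlation of the adipocyte list was 0.67. Splits of the real libraries other than the real one gave up to 11 lists in females, 13 in males and 13 for the difference between sexes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.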

Results

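RNA was sequenced from osteoblast cultures grown from the bone marrow of UM-HET3 mice, a genetically mixed stock, that were 9 months old. The mice had eaten a control diet or a diet with 180 ppm canagliflozin, an inhibitor of the renal glucose transporter SGLT2, for 3 months. Marrow stromal cells of each mouse were expanded for 7 days, placed in osteoblast induction medium from day 8, and harvested at 10 days. The 14 libraries were 3 female control, 3 female canagliflozin, 4 male control and 4 male canagliflozin cultures, 1 library per mouse. The drug was given to the animals, and the labels name no drug in the culture medium. Total counts ran from 4947868 to 7836783 in female control, from 5581292 to 10617990 in female canagliflozin, from 4532751 to 5902544 in male control and from 4785095 to 6204641 in male canagliflozin libraries.

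Markers of several cell types were read in every library. Genes of the macrophage list took 0.89% ± 0.021 (SD, n = 3) of the counts in female control, 0.861% ± 0.245 (SD, n = 3) in female canagliflozin, 1.74% ± 0.158 (SD, n = 4) in male control and 2.26% ± 0.337 (SD, n = 4) in male canagliflozin cultures. Adipocyte genes took 0.805% ± 0.215 and 0.222% ± 0.0968 in female control and canagliflozin, and 0.836% ± 0.182 and 0.632% ± 0.273 in the same male groups. Osteoblast genes took 3.05% ± 0.517 and 5.02% ± 0.807 in females, and 2.61% ± 0.526 and 2.91% ± 0.132 in males. The female osteoblast share was made up largely of the collagen gene Col1a1, whose CPM are given below. Female canagliflozin replicate 1 stood apart. Its first principal component was 58.7 against 34.0 and 35.1 in the other female canagliflozin libraries, its adipocyte score was 3.21 against 4.88 and 5.40, and its macrophage score was 6.99 against 7.86 and 7.84. A score is the mean log2 CPM (counts scaled to a common library size) of a list's genes.

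The first comparison asked what the drug diet changed in cultures from females (3 canagliflozin against 3 control). Genes of fat cells were lower as a group in the canagliflozin cultures. The adipocyte list had a median log2 fold change of -2.21, and 0 of its 23 tested genes were positive. Pparg, the master regulator of fat cell formation, had a log2 fold change of -1.63 ± 0.34 (SE, edgeR adjusted p = 0.133), with 108 ± 26.9 CPM (SD, n = 3) in control and 35.3 ± 15.3 CPM (n = 3) in canagliflozin cultures. Adrb3, the β3-adrenergic receptor, stood at -3.75 ± 0.73 (adjusted p = 0.0884), the triglyceride-synthesis enzyme Dgat2 at -1.64 ± 0.34 (0.0933) and the hormone-sensitive lipase gene Lipe at -2.08 ± 0.49 (0.145). The adipokine gene Adipoq varied more, at -2.12 ± 1.07 (0.544). Adjusted over the list alone, 19 of the 23 genes passed, all lower. Without canagliflozin replicate 1, which stands apart, the list's median was -1.80 and the list still passed. The list passed camera at an adjusted p of 2.93e-16 but not when the correlation between genes was estimated (adjusted p = 0.409 with an estimated correlation).

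Genes of bone matrix and of the osteoblast lineage were higher as groups in the same cultures. In the osteoblast list the median log2 fold change was 0.66, with 21 genes positive and 4 negative. Col1a1, the main collagen of bone, was measured at 29778 ± 5684 CPM (SD, n = 3) against 15583 ± 3363 CPM (n = 3), a log2 fold change of 0.91 ± 0.21 (SE, edgeR adjusted p = 0.115). Sparc, which encodes the matrix protein osteonectin, had 0.66 ± 0.16 (0.136), Cgref1 had 1.19 ± 0.28 (0.118) and the lineage transcription factor Sp7 had 0.71 ± 0.26 (0.327). Cdh11, osteoblast cadherin, pointed the other way at -0.79 ± 0.15 (0.0823). Runx2, the first transcription factor of the lineage, stood at 0.13 ± 0.11 (0.737), the alkaline phosphatase gene Alpl at 0.44 ± 0.22 (0.484), Ibsp at 0.89 ± 0.65 (0.696) and Spp1 at 0.37 ± 0.29 (0.695). Bglap, the osteocalcin gene, was at 2.69 ± 2.44 against 0.882 ± 0.867 CPM, and its reads may be shared with near-identical copies, which was not tested. Adjusted over the list alone, 7 osteoblast genes passed, 6 higher and 1 lower (camera adjusted p = 1.14e-04; adjusted p = 0.409 with an estimated correlation).

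The extracellular matrix list had a median of 0.39 in females, with 29 genes positive and 6 negative. Timp1, an inhibitor of matrix proteases, had a log2 fold change of 0.94 ± 0.15 (SE), Fbln2 0.76 ± 0.16, the gelatinase gene Mmp2 0.64 ± 0.14 and Col5a1 0.82 ± 0.19. Over the list alone 10 of its 35 genes passed, all higher (camera adjusted p = 3.14e-07; adjusted p = 0.409 with an estimated correlation). The ATF4 stress response list, amino acid and one-carbon genes induced by the transcription factor ATF4, had a median of 0.38 with 19 genes positive and 4 negative. Aldh18a1, of proline synthesis, stood at 0.77 ± 0.17 (edgeR adjusted p = 0.112) and was the 1 gene that passed over the list alone, and Mthfd2 stood at 0.77 ± 0.27 (0.274). The camera adjusted p of that list was 0.00101 (adjusted p = 0.409 with an estimated correlation).

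Mitochondrial fuel oxidation genes were lower as groups in female canagliflozin cultures. The fatty acid oxidation list had a median log2 fold change of -0.41, with 25 of 27 genes negative. The acyl-CoA dehydrogenases Acadl and Acadm had -0.85 ± 0.17 and -0.75 ± 0.18 (SE), and were the 2 that passed over the list alone. The tricarboxylic acid cycle list had a median of -0.26 with 23 of 24 genes negative, among them Dld at -0.58 ± 0.15 and Idh2 at -0.50 ± 0.15. The nuclear oxidative phosphorylation list had -0.19 with 66 of 75 negative, among them Cox5b at -0.59 ± 0.18 and Sdha, which the cycle list also holds, at -0.39 ± 0.14. In both of these lists 0 genes passed over the list alone, and Sdha, Sdhb, Sdhc and Sdhd, 4 genes, belonged to both. The camera adjusted p was 3.44e-06 for fatty acid oxidation (adjusted p = 0.409 with an estimated correlation), 7.58e-05 for the cycle (adjusted p = 0.555 with an estimated correlation) and 1.82e-04 for oxidative phosphorylation (adjusted p = 0.734 with an estimated correlation). Fat cells may also express these genes, and adipocyte genes were lower by more in the same libraries (list median -2.21), so a smaller share of fat cell RNA was not separated from a change within cells. Without female control replicate 1 the oxidative phosphorylation list had a median of -0.10 and an adjusted p of 0.109.

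Of the other cell type lists that could be tested in females, none passed with all 6 libraries. The macrophage list had a median of -0.01 (camera adjusted p = 0.923; 0.998 with an estimated correlation), with Cx3cr1 at 1.01 ± 0.34, Mrc1 at -0.36 ± 0.30, Csf1r at -0.26 ± 0.24 and C1qa at -0.18 ± 0.17. Without canagliflozin replicate 1 its median was 0.24 with an adjusted p of 7.65e-04, and C1qa was at 0.01. The osteoclast list had a median of -0.68 (adjusted p = 0.239). It passed at -1.12 without control replicate 3 (2.64e-04), and had -0.21 without canagliflozin replicate 1 (0.966). The cell cycle list had a median of 0.02 with an adjusted p of 0.949, and -0.17 with an adjusted p of 0.0341 without canagliflozin replicate 1. The chondrocyte list (median 0.22, adjusted p = 0.383) passed at 0.46 without control replicate 3 (0.0265) and at 0.51 without canagliflozin replicate 3 (0.0452). These calls without single libraries are camera calls at the preset correlation, and no estimated correlation was run for them. With all 6 libraries and an estimated correlation the adjusted p was 0.987 for the osteoclast, 0.998 for the cell cycle and 0.683 for the chondrocyte list.

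No single gene passed in females: edgeR found 0 of 13374 genes at an adjusted p under 0.05, and the smallest was 0.0565. At an unadjusted p under 0.05 there were 1601 genes, 804 higher and 797 lower, where about 1 in 20 of the genes tested is what chance alone gives. DESeq2 found 444 genes and limma-voom 61. Without canagliflozin replicate 1 edgeR found 165 genes, and without canagliflozin replicate 3 it found 127. It found 0 without control replicate 1, 2 or 3, and 0 without canagliflozin replicate 4. The genes with the smallest p were, on the higher side, Ahnak2 (1.06 ± 0.14, SE), Timp1, the clock-linked repressor Bhlhe40 (1.06 ± 0.17), the dystrophin gene Dmd (1.49 ± 0.24) and Sema7a (1.05 ± 0.17). On the lower side they were Plxna2 (-0.99 ± 0.14), the protocadherin Fat4 (-0.90 ± 0.13), Net1 (-0.94 ± 0.14), the GABA transaminase Abat (-1.33 ± 0.19) and Deptor, an inhibitor of mTOR (-1.32 ± 0.19). Each of these 10 had an adjusted p of 0.0565. The osteoclast-inducing cytokine gene Tnfsf11 stood at -1.09 ± 0.40 (0.294), its decoy receptor Tnfrsf11b at -0.08 ± 0.33 (0.963), Igf1 at -0.27 ± 0.20 (0.669) and the glucose transporter Slc2a1 at -0.08 ± 0.18 (0.924). The directions of Tnfrsf11b and Slc2a1 turned when single libraries were left out. Slc5a2, which encodes the drug's target, had 31 reads over all 14 libraries and Slc5a1 had 56, too few to test.

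**Figure D1:**
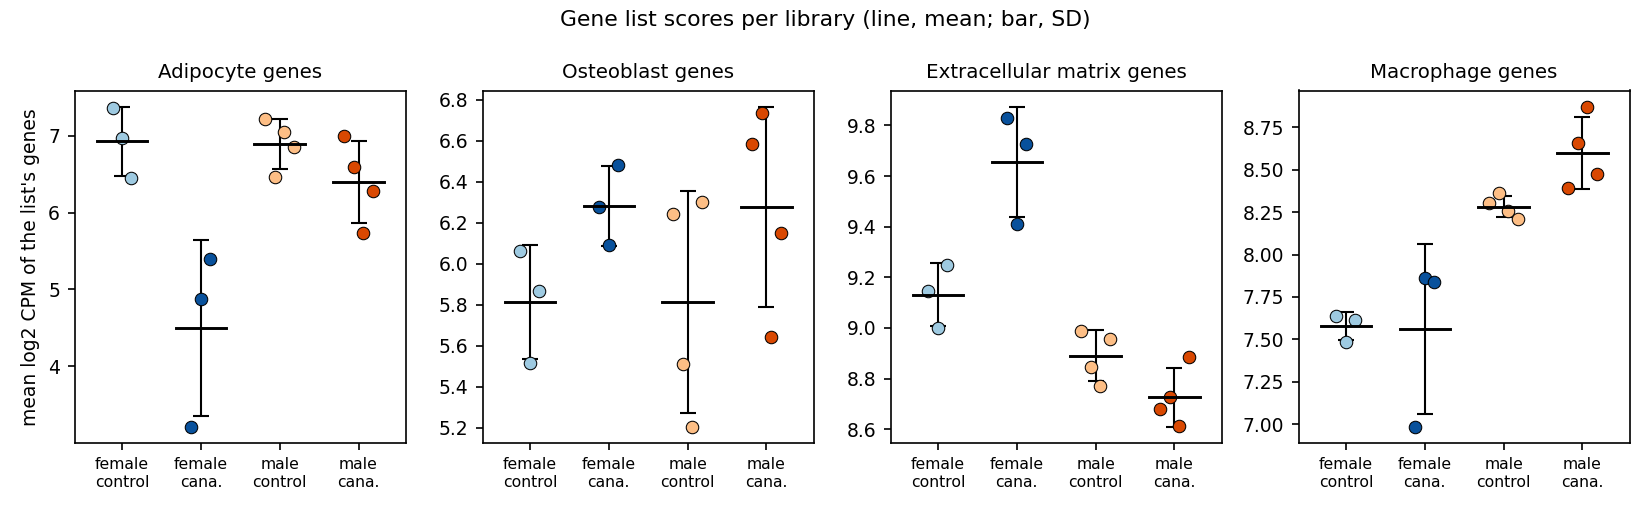
Mean log2 CPM of the genes of 4 lists in each library (points), with the group mean (line) and SD (bar), for 3 female control, 3 female canagliflozin, 4 male control and 4 male canagliflozin libraries. The 3 female canagliflozin libraries have adipocyte scores of 3.21 to 5.40, below the 6.45 to 7.36 of the female controls.

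Per library, the female adipocyte score was 4.5 ± 1.14 (SD, n = 3) with canagliflozin and 6.93 ± 0.455 (n = 3) on control diet. The matrix score was 9.66 ± 0.219 against 9.13 ± 0.124, the osteoblast score 6.28 ± 0.197 against 5.81 ± 0.276, and the stromal progenitor score 6.52 ± 0.131 against 6.82 ± 0.103. In each of these the groups did not overlap, which chance gives in 10% of splits of 3 against 3. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 allows, and 0.233 after adjustment over 28 tests of library measures.

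The same question in males (4 canagliflozin against 4 control) gave 51 genes, 9 higher and 42 lower, at an edgeR adjusted p under 0.05 among 12838 tested. Bmp4, a bone morphogenetic protein gene on chromosome 14 (46383525 to 46390669, GRCm38), fell from 94.5 ± 15.9 CPM (SD, n = 4) to 33.8 ± 8.93 CPM (n = 4), a log2 fold change of -1.49 ± 0.18 (SE, adjusted p = 0.00841). Igfbp3, an IGF carrier protein gene on chromosome 11 (7206086 to 7215498), had the lowest log2 fold change of the genes named here, -2.73 ± 0.38 (0.0306). Kitl, the stem cell factor gene, fell (-0.81 ± 0.13, 0.0241). Cxcl12, the chemokine that holds blood stem cells in marrow, fell from 6941 ± 1064 to 3745 ± 806 CPM (-0.90 ± 0.16, 0.0306). Among the higher genes, Spp1, the osteopontin gene, rose from 1424 ± 136 to 3004 ± 877 CPM (1.07 ± 0.19, 0.0426). Gpnmb, a glycoprotein of macrophages and osteoblasts, rose as well (1.11 ± 0.20, 0.0473).

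The other higher genes were Prokr1, a prokineticin receptor, at 2.32 ± 0.41 (SE) with 2.11 ± 0.666 CPM in control and 10.7 ± 1.6 CPM in canagliflozin cultures, Bst1 at 1.31 ± 0.21, Lrp8 at 1.21 ± 0.23, Arl4c at 1.05 ± 0.17, the sialic acid enzyme Npl at 0.97 ± 0.15, Lhfpl2 at 0.60 ± 0.12 and thioredoxin reductase Txnrd1 at 0.50 ± 0.10. Among the genes that met the naming rule, the largest falls after Igfbp3 were in Clec14a (-2.51 ± 0.51), Adrbk2, now called Grk3 (-2.37 ± 0.42), the anion exchanger Slc26a7 (-2.22 ± 0.40) and Cbln1 (-2.14 ± 0.38). Fmo1 (-1.64 ± 0.26), Efemp1 (-1.59 ± 0.29), the complement gene C1s1 (-1.51 ± 0.23) and, after Bmp4, the smooth muscle gene Lmod1 (-1.44 ± 0.28) followed.

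**Figure D2:**
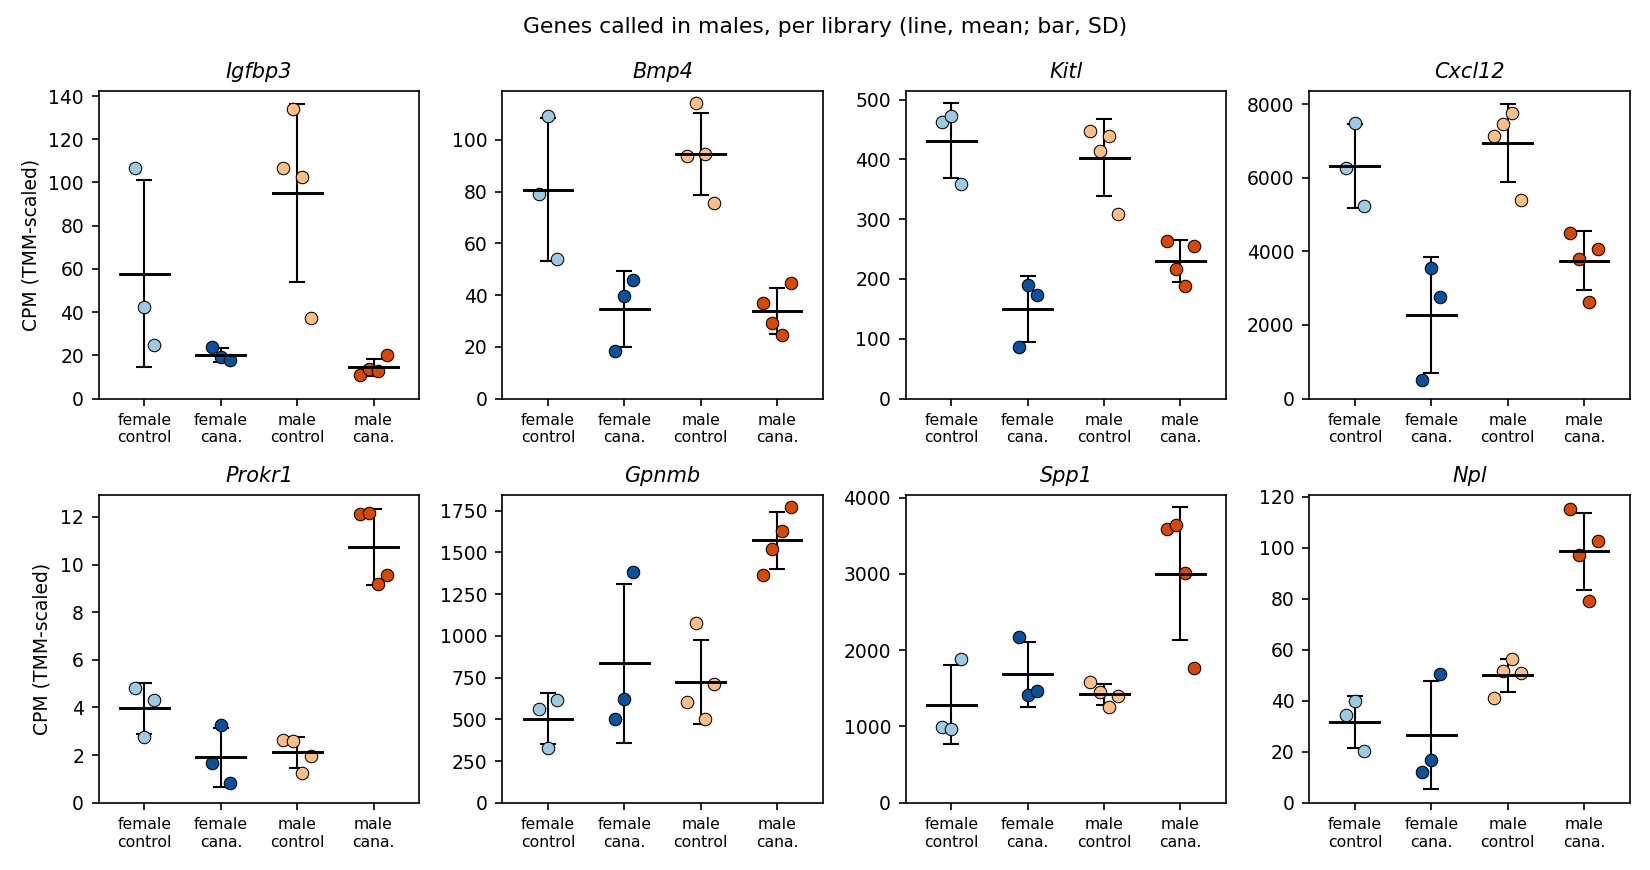
TMM-scaled CPM of 8 genes past the threshold in males, in each of the 14 libraries (points), with the group mean (line) and SD (bar). Bmp4 averages 94.5 CPM in male control and 33.8 CPM in male canagliflozin libraries, and Prokr1 averages 2.11 and 10.7 CPM.

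The male count moved with single libraries. It was 2 without control replicate 1, 6 without control replicate 2, 5 without control replicate 3 and 81 without control replicate 4. It was 90 without canagliflozin replicate 1, 2 without replicate 3, 28 without replicate 4 and 91 without replicate 7. In each of these fits all 51 genes kept their sign, in libraries that had also served to choose them. Bmp4 had -1.66 to -1.37 over 17 alternatives and missed the threshold in 1 of them, the fewest among the named genes that passed. Over the same alternatives Clec14a missed it in 11, Gpnmb in 10, Spp1 in 9 and Igfbp3 in 8. DESeq2 found 211 genes, a fit of all 4 groups with a shared spread found 2, and 27 of the 51 also had an absolute log2 fold change above 1. With each library's macrophage score as a covariate, a fit chosen after the data were seen, 1 gene passed. In it the 51 genes had the same sign, with medians of -0.76 for the lower and 0.95 for the higher ones in place of -0.98 and 1.07, and the median SE was 0.245 in place of 0.174.

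Macrophage genes were higher as a group in male canagliflozin cultures, with a median log2 fold change of 0.31 and 19 of 20 genes positive. The microglia and macrophage chemokine receptor Cx3cr1 stood at 1.32 ± 0.36 (SE, edgeR adjusted p = 0.187), lysozyme Lyz2 at 0.47 ± 0.14 (0.212), the cathepsin Ctss at 0.51 ± 0.16 (0.248) and Fcer1g at 0.36 ± 0.12 (0.25). Adjusted over the list alone 6 genes passed, all higher (camera adjusted p = 3.13e-05; adjusted p = 0.405 with an estimated correlation). No gene of this list is held by another list used here. The macrophage score was 8.60 ± 0.213 (SD, n = 4) against 8.28 ± 0.0639 (n = 4), and the marrow stromal progenitor score 6.23 ± 0.164 against 6.46 ± 0.0785. For both, the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 allows, and 0.233 after adjustment over 28 tests.

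Genes of marrow stromal progenitors and contractile cells were lower as groups in males, beside the higher macrophage genes. The smooth muscle list had a median of -0.70 with 11 of 12 genes negative, 5 of them past over the list alone and all lower. Mylk, the myosin light chain kinase, fell (-0.65 ± 0.13, SE, edgeR adjusted p = 0.0473), and Actg2, whose reads may include those of other actins, stood at -0.66 ± 0.19 (0.215). The camera adjusted p was 8.27e-06 (adjusted p = 0.405 with an estimated correlation). The stromal progenitor list had a median of -0.46, with 9 of 17 genes negative and 8 past over the list alone, all lower (camera adjusted p = 0.00414; adjusted p = 0.405 with an estimated correlation). Beside Kitl and Cxcl12 it held Vcam1 at -1.05 ± 0.21 (0.0737) and the transcription factor Foxc1 at -0.66 ± 0.15 (0.0779). The osteoclast regulator list, which shares Cxcl12, had a median of -0.55 with 8 of 9 genes negative and 3 past over the list alone (camera adjusted p = 8.42e-04; adjusted p = 0.405 with an estimated correlation). In it Tnfsf11 stood at -0.97 ± 0.34 (0.293), Il34 at -0.78 ± 0.24 (0.212) and Tnfrsf11b at 0.14 ± 0.23 (0.899).

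The male insulin and IGF axis list had a median of -0.26 with 10 of 15 genes negative. Beside Igfbp3 it held Igfbp4 at -0.66 ± 0.15 (SE, edgeR adjusted p = 0.0742), the growth hormone receptor Ghr at -0.80 ± 0.20 (0.145) and Igf1 at 0.36 ± 0.15 (0.38). Over the list alone 4 genes passed, all lower (camera adjusted p = 0.00398; adjusted p = 0.405 with an estimated correlation). The adipocyte list had a median of -0.46 with 22 of 23 genes negative and 0 past over the list alone (camera adjusted p = 1.67e-04; adjusted p = 0.577 with an estimated correlation). Slc2a4, the insulin-regulated glucose transporter, stood at -1.03 ± 0.35 (0.275), the lipase Pnpla2 at -0.53 ± 0.18 (0.293), Pparg at -0.43 ± 0.21 (0.485) and Adipoq at -0.53 ± 0.26 (0.52). Cd36, the exception, stood at 0.37 ± 0.13 (0.313). The fatty acid oxidation list had a median of -0.18 with 21 of 27 negative and 0 past over the list alone (camera adjusted p = 0.013; adjusted p = 0.405 with an estimated correlation), with Ppara at -1.54 ± 0.58 and Acads at 0.62 ± 0.24. It did not pass without control replicate 3 (0.0628) or canagliflozin replicate 7 (0.0598).

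Higher lists in males were the ATF4 stress response, glycolysis, ribosomal proteins and osteoblast genes. The ATF4 list had a median of 0.36 with 19 of 22 genes positive and 3 past over the list alone, among them Nupr1 at 0.58 ± 0.16 (SE) and Slc3a2 at 0.56 ± 0.16 (camera adjusted p = 7.75e-04; adjusted p = 0.426 with an estimated correlation). Without canagliflozin replicate 1 it had 0.23 and an adjusted p of 0.0586. The glycolysis list had 0.15 with 16 of 21 positive, Pkm at 0.46 ± 0.10 (edgeR adjusted p = 0.0645) and Ldhb at -0.99 ± 0.29 (0.198), these 2 past over the list alone (camera adjusted p = 0.0122; adjusted p = 0.426 with an estimated correlation). It had an adjusted p of 0.135 without canagliflozin replicate 1. The ribosomal list had 0.09 with 40 of 56 positive, among them Rpl37 at 0.65 ± 0.15, the 1 past over the list alone, and Rps3 at 0.26 ± 0.09 (camera adjusted p = 0.00414; adjusted p = 0.405 with an estimated correlation), with reads shared with pseudogene copies left open. Macrophage genes were higher in the same libraries (list median 0.31), and a change in cell shares was not separated from these shifts.

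The osteoblast list had a median of 0.19 in males with 16 of 24 genes positive. Spp1 and Cdh11 passed over the list alone, 1 higher and 1 lower, with Cdh11 at -0.53 ± 0.11 (SE, edgeR adjusted p = 0.0545). Ibsp stood at 1.17 ± 0.51 (0.486), Sp7 at 0.41 ± 0.26 (0.636), Bglap at 1.10 ± 1.09 (0.791), Runx2 at -0.14 ± 0.13 (0.753), Alpl at 0.10 ± 0.21 (0.919), Col1a1 at 0.12 ± 0.19 (0.893) and Slc2a1 at 0.12 ± 0.18 (0.889). The signs of Alpl, Col1a1, Slc2a1 and Tnfrsf11b turned when single libraries were left out. The camera adjusted p of the list was 0.042 (adjusted p = 0.793 with an estimated correlation). It was 0.29 without control replicate 2, 0.212 without control replicate 3, 0.169 without canagliflozin replicate 1 and 0.189 without canagliflozin replicate 3.

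Matrix, cartilage and cell cycle lists were lower in males. The extracellular matrix list had a median of -0.11 with 22 of 35 genes negative and 6 past over the list alone, 1 higher and 5 lower (camera adjusted p = 0.0136; adjusted p = 0.405 with an estimated correlation). Loxl1, a collagen and elastin crosslinking enzyme, fell (-0.67 ± 0.11, SE, edgeR adjusted p = 0.0241), and Vcan stood at -0.62 ± 0.18 (0.209). The matrix list had an adjusted p of 0.0604 without control replicate 1, 0.0894 without control replicate 4 and 0.0757 without canagliflozin replicate 1. The chondrocyte list, with Sox9 at -0.86 ± 0.33, had a median of -0.50 with 6 of 6 genes negative and 0 past over the list alone (camera adjusted p = 0.0304; adjusted p = 0.405 with an estimated correlation). It had adjusted p of 0.127 and 0.0894 without control replicates 1 and 4, and 0.174 and 0.0756 without canagliflozin replicates 1 and 3. The cell cycle list, with Ccnb2 at -1.05 ± 0.33, had -0.20 with 24 of 30 negative and 0 past over the list alone (camera adjusted p = 0.042; adjusted p = 0.793 with an estimated correlation). Without control replicates 2 and 3 its adjusted p was 0.29 and 0.538, and without canagliflozin replicates 3, 4 and 7 it was 0.0677, 0.478 and 0.568.

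**Figure D3:**
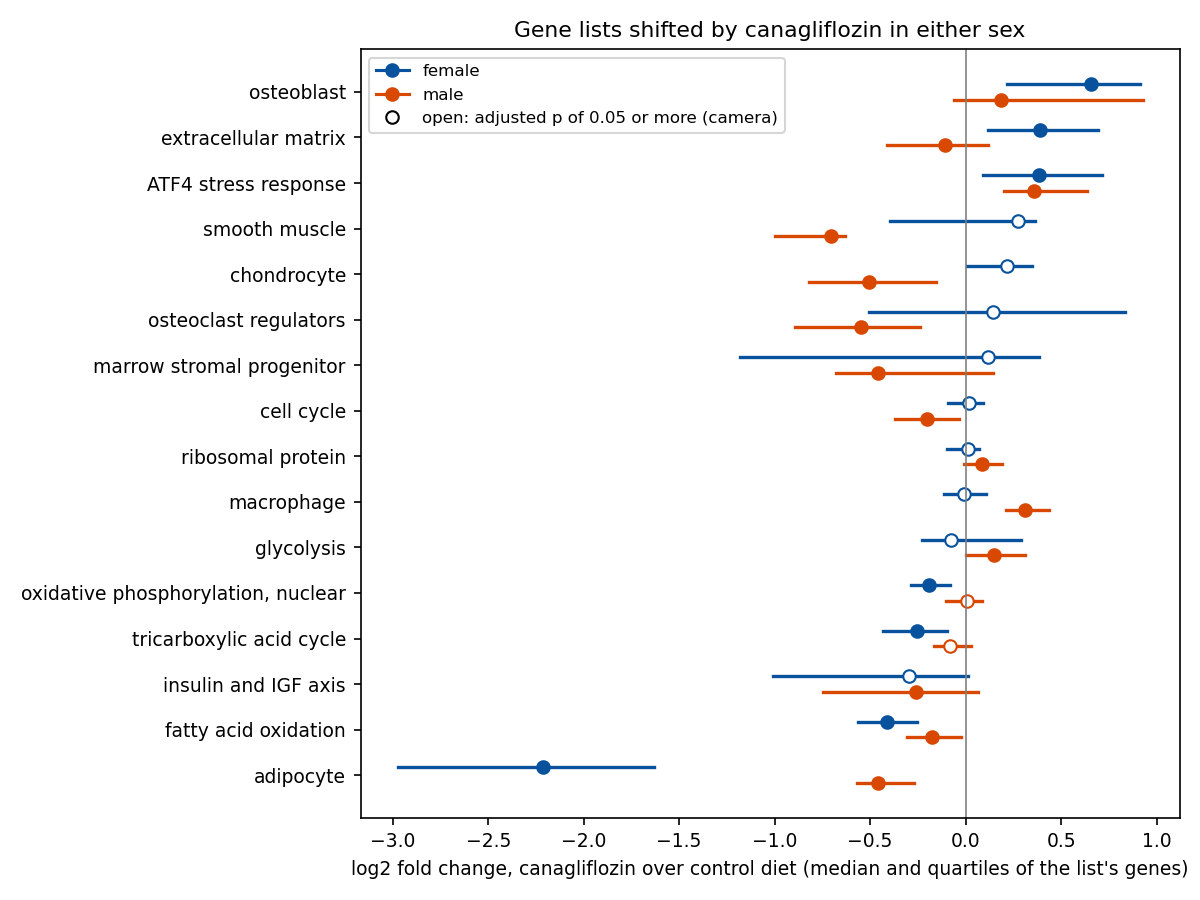
Median (point) and quartiles (bar) of the log2 fold changes, canagliflozin over control, of each gene list past a camera adjusted p of 0.05 in females (3 against 3 libraries) or in males (4 against 4), with open points where the list did not pass in that sex. The adipocyte median is -2.21 in females and -0.46 in males, and the macrophage median is -0.01 and 0.31.

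Whether the diet acted differently in the 2 sexes was tested as the difference of the female and male effects, with 14248 genes in a fit of all 14 libraries. Fat cell genes differed most as a group: the adipocyte list had a median difference, female minus male, of -1.74, with 22 of 23 genes negative and 3 past over the list alone, all lower. Matrix genes differed the other way, with a median of 0.52, 32 of 35 genes positive and 5 past over the list alone, all higher. The smooth muscle list had a difference of 0.96 and the chondrocyte list 0.85, both higher in females relative to males. The macrophage list had -0.29, oxidative phosphorylation -0.19, the tricarboxylic acid cycle -0.19, fatty acid oxidation -0.21 and glycolysis -0.21. In these 7 lists, 1 smooth muscle gene passed over the list alone, higher, and 0 genes of the other lists did.

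The camera adjusted p of the difference was 4.73e-16 for adipocyte genes (adjusted p = 0.314 with an estimated correlation), 7.68e-12 for matrix genes (adjusted p = 0.137 with an estimated correlation) and 9.65e-04 for smooth muscle (adjusted p = 0.498 with an estimated correlation). It was 0.0397 for chondrocyte genes (adjusted p = 0.314 with an estimated correlation), 0.0028 for macrophage genes (adjusted p = 0.67 with an estimated correlation) and 0.00154 for oxidative phosphorylation (adjusted p = 0.67 with an estimated correlation). For the tricarboxylic acid cycle it was 0.0171 (adjusted p = 0.67 with an estimated correlation), for fatty acid oxidation 0.0171 (adjusted p = 0.348 with an estimated correlation) and for glycolysis 0.0239 (adjusted p = 0.498 with an estimated correlation). The fry test, which asks whether a list's genes move one way on balance, gave an adjusted p of 0.0368 for matrix genes and 0.263 for adipocyte genes. Within each sex, none of the lists fixed beforehand passed fry. The smallest fry adjusted p was 0.0839 in females and 0.117 in males. The osteoblast list had a difference of 0.33 that did not pass (0.306).

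Single libraries ended several of these calls. Without female canagliflozin replicate 1 the macrophage difference was -0.13 (adjusted p = 0.552), while the adipocyte difference was -1.41 and still passed. Without female control replicate 1, 5 lists passed in place of 9, and oxidative phosphorylation (0.122), the tricarboxylic acid cycle (0.186), fatty acid oxidation (0.104) and glycolysis (0.104) did not. Fatty acid oxidation and glycolysis (both 0.0514) and the chondrocyte list (0.075) also did not pass without female canagliflozin replicate 4, nor glycolysis (0.0532) without female canagliflozin replicate 3. The chondrocyte list did not pass without male control replicate 1 (0.0659) or male canagliflozin replicate 1 (0.077), and the latter also ended glycolysis (0.0921). The tricarboxylic acid cycle did not pass without male control replicate 2 (0.0502) or male canagliflozin replicates 1 (0.0921) and 3 (0.0513).

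Per library, the matrix score differed by 0.52 between diets in females and by -0.16 in males, a difference of 0.69 between the sexes. An exact two-sided permutation test of the diet labels within each sex, 1400 arrangements, gave p = 0.00429, or 0.0214 adjusted over 5 scores. For the adipocyte score the difference was -1.94 (exact permutation p = 0.131, adjusted 0.329), for the macrophage score -0.33 (p = 0.32, adjusted 0.533), for the stromal score -0.08 (p = 0.733, adjusted 0.916) and for the osteoblast score 0.01 (p = 0.993, adjusted 0.993). These score tests were added after the list results were seen, and their null is no diet effect in either sex.

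No gene passed for the difference between sexes: edgeR found 0, with a smallest adjusted p of 0.422, against 960 at an unadjusted p under 0.05. DESeq2 found 26 and limma-voom 0. Without female canagliflozin replicate 4 edgeR found 2. The genes with the smallest p, each at an adjusted p of 0.422, were Galnt10 (female minus male log2 difference 1.13 ± 0.24, SE), Dtna (1.84 ± 0.39), Grik5 (3.90 ± 0.84), Lhfp (0.80 ± 0.18) and Tgfb3 (0.93 ± 0.21) on one side. On the other were Prokr1 (-3.40 ± 0.72), the semaphorin and VEGF co-receptor Nrp1 (-0.65 ± 0.15), Vps26a (-0.64 ± 0.15), Adrb3 (-3.06 ± 0.75) and Npr1. Npr1, a natriuretic peptide receptor, had 113 reads in the female control and 3 in the female canagliflozin libraries, a ratio of 46.1 (95% counting interval, exact Clopper-Pearson, 15.4 to 227). In males it had 12.4 ± 6.73 CPM (SD, n = 4) on control diet and 8.42 ± 4.40 CPM (n = 4) with canagliflozin. Such intervals cover counting error only.

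Across the 12573 genes tested in both sexes, the female and male log2 fold changes had a Pearson correlation of 0.30 and a Spearman correlation of 0.24. Genes are not independent replicates, so no p is given. At an unadjusted p under 0.05 in each sex, 246 genes were lower in both, against 48.3 from the products of the counts, and 124 were higher in both, against 35.2. Higher in females and lower in males were 28, against 44.9, and the reverse held for 9, against 37.8. Of the 51 genes that passed in males, 50 were tested in females and 45 of these had the same sign there, 26 of them with an unadjusted p under 0.05. Kitl, for example, had -1.55 ± 0.29 (SE, edgeR adjusted p = 0.114) in females.

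**Figure D4:**
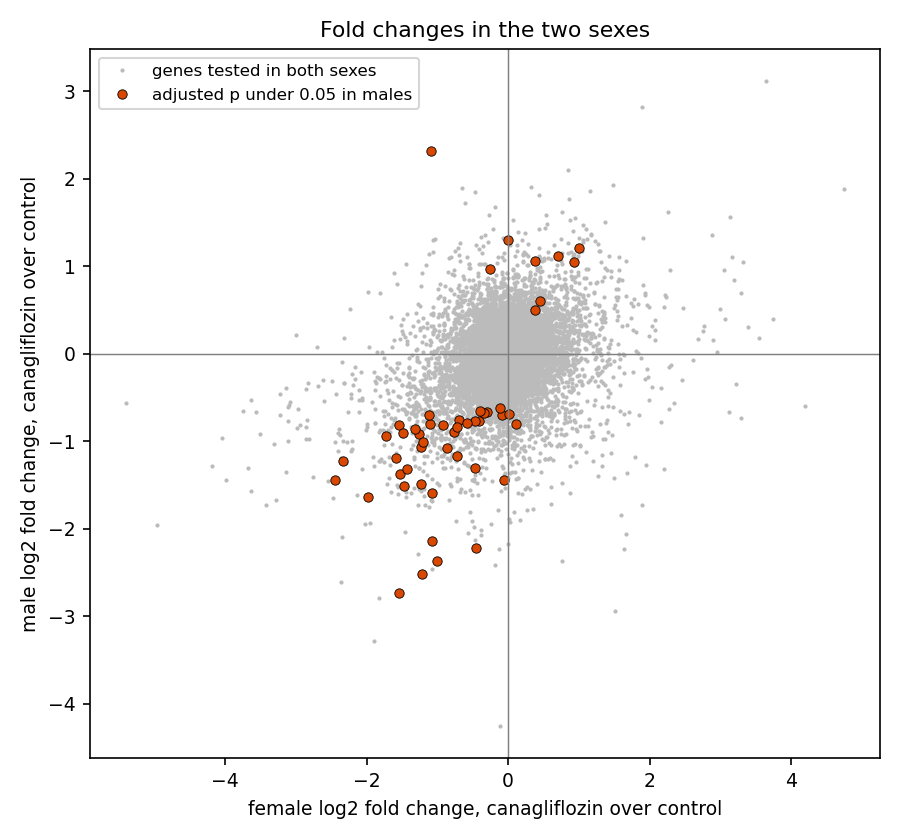
Female (x) and male (y) log2 fold changes, canagliflozin over control, of the 12573 genes tested in both sexes (grey), with the 50 of the genes past the threshold in males that were tested in females in color. Of these, 45 have the same sign in both sexes, and Prokr1 is at 2.32 in males.

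Male and female control cultures were compared with the limit that each sex was deposited as its own table, so that sex and any difference between the tables cannot be told apart. Genes of the sex chromosomes matched the labels. Xist, the RNA that silences an X chromosome, stood at 1081 ± 137 CPM (SD, n = 3) in female and 2.1 ± 2.27 CPM (n = 4) in male controls. The Y-linked genes Ddx3y (84.2 ± 4.55 CPM in males), Uty (63.9 ± 8.02), Eif2s3y (57.0 ± 6.10) and Kdm5d (42.6 ± 6.09) had 0 reads in the 3 female control libraries. Against a floor of 3 counts over that group, 0.168 CPM, their means were at least 503-fold, 381-fold, 340-fold and 254-fold higher in males.

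In all, 255 genes passed between the sexes on control diet, 123 higher in females and 132 higher in males (edgeR). Higher in females were the neurotrophin gene Bdnf (log2 fold change 3.94 ± 0.60, SE, adjusted p = 0.00199), Coch (3.66 ± 0.78) and Ptprq (4.35 ± 1.01). H2-M9, which has close relatives in the same gene family, had 48 reads in female and 0 in male controls, a mean at least 16.8-fold higher against a floor of 3 counts over the male group (0.146 CPM). Gfra3 had 39 reads and 1, a ratio of 44.6 (95% counting interval, exact Clopper-Pearson, 7.55 to 1807). Higher in males were Nxpe5 (-2.46 ± 0.21, adjusted p = 6.47e-07), Ch25h, which makes 25-hydroxycholesterol (-2.14 ± 0.43), Ralgps2 (-2.07 ± 0.45), Bmp2 (-1.94 ± 0.34) and the interleukin receptor Il21r (-1.86 ± 0.45). Macrophage scores were also higher in male controls (8.21 to 8.36) than in female controls (7.49 to 7.64). A difference in cell shares was not separated from the genes that passed between the sexes. DESeq2 found 585 genes and limma-voom 568. Left-out libraries moved the edgeR count to 115, 76 and 64 (female control replicates 1, 2 and 3), to 117, 91 and 157 (male control replicates 1, 2 and 3) and to 429 (female canagliflozin replicate 1, which shares the fit).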

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

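Tests chosen only after the result was seen are those on female canagliflozin replicate 1 within females, on the share of macrophages in females, on dilution and macrophage share in males, on male libraries held out in pairs, the thinned libraries, the macrophage covariate and the score tests between sexes.

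Fat cell genes were lower in female canagliflozin cultures, with a list median log2 fold change of -2.21. One library that stands apart was argued against as the whole cause, since the median was -1.80 without canagliflozin replicate 1, and so was sequencing depth, with -2.20 in libraries thinned to the smallest female total. A larger share of macrophages as the whole cause would lower osteoblast and matrix genes with the fat cell genes, but their medians were 0.66 and 0.39, while the macrophage median was -0.0098 with all libraries and 0.24 without canagliflozin replicate 1 (camera adjusted p = 7.65e-04). The diet remains a hypothesis for this pattern, and whether the cultures held fewer fat cells or cells with lower fat cell genes stays open. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 7 lists, the highest other 11, and the median of the others was 5. The real split and the highest other both gave 0 genes.

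In males, 42 genes were lower and 9 higher with canagliflozin while macrophage genes were higher. Dilution of stromal RNA by macrophage RNA as the whole cause was argued against, since it would lower osteoblast and matrix genes alike. Of these, 59 had a median of -0.047 (quartiles -0.31 and 0.26). For 42 lower genes chosen in 3 against 3 libraries and measured in the pair held out, the median over pairs was -0.61. The 42 genes that passed had -0.98 (quartiles -1.44 and -0.79), but they were chosen in these same libraries, so their low values are no evidence here. Were 1 library the whole cause of the lower genes, held-out pairs without it would lie near 0. The held-out median was below 0 in 16 of 16 pairs (-1.38 to -0.13), but these pairs reuse the same 8 libraries. It was weakest over the pairs with control replicate 4 (-0.37) and with canagliflozin replicate 7 (-0.44). The rule written for this test asked for a lower median than these in every library. The test therefore does not decide whether 1 library was the whole cause, and how much single libraries add stays open. A larger macrophage share stays open for the higher genes, whose held-out median exceeded that of the macrophage list by 0.16 and its upper quartile in 7 of 16 pairs. With the macrophage score in the fit, the count went from 51 to 1, the medians from -0.98 to -0.76 and from 1.07 to 0.95, and the median SE from 0.174 to 0.245. Folds were smaller and errors wider, and how many calls each ended was not tested. The score did not overlap between the diets (8.21 to 8.36 in control, 8.39 to 8.87 in canagliflozin), which by itself widens the errors. The lost calls therefore do not show that macrophage content accounts for them. The real split gave 51 genes, the only 1 of 35 with as many, against 33 in the highest other. A share of 1 in 35 is the smallest these splits allow, and it was not adjusted over the split tests. It argues against chance for the count of genes without excluding it. The count of lists at the preset correlation led by a margin of 1 list (14 against 13, also 1 of 35), and the other splits had a median of 6. Chance is not excluded for the lists, and 0 of the 14 passed with an estimated correlation.

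At the preset correlation, but in 0 lists with an estimated one, the female and male diet effects differed in 9 lists by the test of the difference, female minus male: adipocyte -1.74, macrophage -0.29, chondrocyte 0.85, smooth muscle 0.96, nuclear oxidative phosphorylation -0.19, glycolysis -0.21, tricarboxylic acid cycle -0.19, fatty acid oxidation -0.21 and extracellular matrix 0.52. The matrix score per library differed by 0.69 (exact permutation, adjusted p = 0.0214). For adipocyte genes, female canagliflozin replicate 1 as the whole cause was argued against by a difference of -1.41 without it. Chance cannot be excluded for the count of lists, since 8 of 60 splits gave at least 9, the highest other gave 13 and the median of the others was 6. Sex is an open explanation that was not tested apart from the tables, which could differ in preparation.

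Single libraries far from the other 3 of their male group were found in 11 of 197 sets of 4 values, and chance gives about 1 in 20. In male control these were replicate 1 for Fmo1 (190 CPM, the others 88.4 to 103) and Bglap (4.30, the others 0 to 0.601), replicate 2 for Rps3 (173, the others 160 to 162) and for Gfra3 (0.200 CPM from 1 read, the others at 0), replicate 3 for Acads (24.4, the others 13.4 to 14.2) and Ccnb2 (30.4, the others 19.4 to 20.7), and replicate 4 for Lyz2 (9285, the others 6885 to 7092) and Npc1 (288, the others 191 to 197). In male canagliflozin they were replicate 1 for Ppara (3.25, the others 1.25 to 1.5) and replicate 3 for Cx3cr1 (61.2, the others 20 to 23.2) and Vps26a (128, the others 119).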

How the results depend on the processing

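The macrophage covariate and the thinned libraries were chosen after the data were seen, and the other alternatives before. The cause was not tested for any change below, except that settings with fewer libraries or another gene filter also change what is tested. RLE and upper quartile scaling gave 0 female genes, 0 for the difference between sexes, 51 and 55 male genes and 245 and 244 between the sexes, and RLE gave 7, 14 and 9 lists. Female genes numbered 444 with DESeq2, 61 with limma-voom, 769 with no filter, 23 with a CPM filter, 121 in the fit of all 4 groups, and 0 to 165 with single libraries left out. Male genes numbered 211 with DESeq2, 74 with limma-voom, 428 with no filter, 2 in the fit of all 4 groups, 27 with an absolute log2 fold change above 1, 1 with the macrophage covariate, and 2 to 91 with single libraries left out. Genes for the difference between sexes numbered 26 with DESeq2, 142 with no filter, and 0 to 2 with single libraries left out. Genes between the sexes on control diet numbered 585 with DESeq2, 568 with limma-voom, 729 with no filter, and 64 to 429 with single libraries left out. With an estimated correlation, 0 lists passed in females, 0 in males and 0 for the difference. With single libraries left out the lists numbered 6 to 10, 10 to 14 and 5 to 12, and 7 female lists passed in thinned libraries.

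The rank correlation of fold changes between sexes, 0.235, was 0.257 above a mean log2 CPM of 3 and 0.191 to 0.25 with single libraries left out. With DESeq2 fold changes it was 0.119, but over all genes with reads in both sexes, without the expression filter. The change of method was not separated from the change of gene set. With the replicate number as a block, 9 genes passed in females, 223 in males and 7 for the difference. Female control replicate 2 and canagliflozin replicate 4 share their number with no library of the other diet. The same holds for male control replicate 2 and canagliflozin replicate 7. In the block fit these libraries add nothing to the diet effect, which rests on fewer libraries than the main fit. Correlations of deviations between libraries of the same number were 0.023 and 0.011 in females and 0.088, -0.057 and 0.071 in males, so the numbers were not read as pairs, and a block could not be had for the sexes on control diet. The block turned female Bglap (-0.16) and Ibsp (-0.086), male Alpl (-0.034) and Col1a1 (-0.040), the female ribosomal list (-0.042), and the direction of camera alone, with the median's sign kept, for female (0.14) and male cell cycle (-0.068) and male oxidative phosphorylation (0.016). The CPM filter turned the test of male oxidative phosphorylation (0.011). With single libraries left out, ranges that held a turned direction were, in females, -0.18 to 0.012 for Slc2a1, -0.35 to 0.23 for Tnfrsf11b and -0.29 to 0.011 for C1qa. For female list medians they were -0.17 to 0.24 for macrophage, -0.17 to 0.15 for cell cycle and -0.036 to 0.048 for ribosomal genes. For smooth muscle (0.097 to 0.38) and osteoclast genes (-1.12 to -0.21) the medians kept their sign and only the direction of camera turned. In males they were -0.081 to 0.25 for Alpl, -0.0092 to 0.32 for Col1a1, -0.00057 to 0.18 for Slc2a1, -0.072 to 0.29 for Tnfrsf11b and -0.035 to 0.020 for the oxidative phosphorylation list. Over all named genes and alternatives, 2085 values kept their direction and side of the threshold, 234 moved past it, 218 no longer passed and 14 turned. On simulated data at these depths and group sizes, 2-fold changes were recovered in 38.8% (female) and 47.8% (male) and 1.5-fold changes in 1.49% and 14.9%, and depth was not varied there.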

Other observations

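Of the tests here, the lysosomal one was chosen only after its result was seen. The amino acid and peroxisome lists were chosen after the leading genes were seen but before their own values were, and which lists that did not pass to describe was chosen after their values were seen.

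Stromal, Wnt and insulin lists that did not pass in females held genes that passed over the list alone. In the first, 7 of 19 stromal progenitor genes did so, 3 higher and 4 lower. Cd44, the hyaluronan receptor, stood at 0.73 ± 0.16 (SE, edgeR adjusted p = 0.112), Foxc1 at -1.02 ± 0.22 (0.114), Kitl at -1.55 ± 0.29 (0.114) and Vcam1 at -1.34 ± 0.29 (0.136). The list's median was 0.12 while its mean was -0.21 and its score per library differed by -0.31 (exact permutation p = 0.1, the smallest possible), and camera pointed down without passing (adjusted p = 0.433). In the female Wnt list 7 of 25 genes passed over the list alone, 5 higher and 2 lower, with Wisp1 at 1.02 ± 0.24 (0.143), Wnt10b at 1.67 ± 0.45 (0.152), Rspo3 at -0.96 ± 0.20 (0.0943) and Nkd1 at -1.38 ± 0.37 (0.16). Its median was -0.12 (camera adjusted p = 0.949). In the female insulin and IGF list 2 of 16 passed over the list alone, Igfbp4 at -0.92 ± 0.16 (0.0605) and the insulin receptor Insr at -0.67 ± 0.15 (0.112), with a median of -0.30 (camera adjusted p = 0.119).

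In males, 8 of 28 genes of the BMP and TGF-beta list passed adjusted over the list alone, 2 higher and 6 lower. Beside Bmp4, Id4, a BMP-induced transcriptional inhibitor, fell (-1.17 ± 0.20, SE, edgeR adjusted p = 0.0306), and so did Tgfbr3, the betaglycan gene (-0.80 ± 0.14, 0.0288), while Bmp2 stood at 1.18 ± 0.27 (0.0904). The list's median was -0.18 and it did not pass (camera adjusted p = 0.0648). In the male Wnt list 5 of 24 passed over the list alone, 1 higher and 4 lower. The Wnt antagonist Sfrp1 fell (-0.76 ± 0.15, 0.0438), and the R-spondins Rspo3 and Rspo2 stood at -0.97 ± 0.22 (0.0931) and -0.77 ± 0.20 (0.184) and Nkd1 at -1.59 ± 0.42 (0.145). Its median was -0.13 (camera adjusted p = 0.245).

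Branched-chain amino acid catabolism genes not among the leading genes had a median of -0.46 in females with 19 of 20 negative, with Bckdhb at -1.09 ± 0.26 and Hsd17b10 at -0.99 ± 0.24 (camera adjusted p = 4.09e-07 over 3 lists; adjusted p = 0.173 with an estimated correlation). Over the list alone 2 passed. In males the median was -0.23 with 18 of 20 negative (0.0011; adjusted p = 0.0724 with an estimated correlation). Peroxisomal lipid genes had a median of -0.35 in females with 15 of 19 negative and 0 past over the list alone, with Pex19 at -0.50 ± 0.16 and Pex11a at -1.23 ± 0.39 (camera adjusted p = 0.00366; adjusted p = 0.173 with an estimated correlation). In males it was -0.02 (0.215). Lysosomal genes had a median of 0.18 in males with 25 of 29 positive and 0 past over the list alone, with Npc1 at 0.44 ± 0.14 and Ctsz at 0.31 ± 0.12 (camera adjusted p = 5.36e-04; adjusted p = 0.356 with an estimated correlation). They had -0.03 in females (0.837). The calls rest on the preset correlation. In the same cultures adipocyte genes were lower in females (list median -2.21) and macrophage genes higher in males (0.31), and a change in cell shares was not separated from these shifts.

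A trade between bone and fat genes within groups was not found. Deviations of the osteoblast and adipocyte scores from their group means had a Pearson r of 0.38 over 14 libraries (permutation p = 0.11) and a Spearman rho of 0.42 (permutation p = 0.105), with r = 0.50 without the 2 farthest libraries. Within females r was 0.22 (permutation p = 0.665) and within males 0.64 (permutation p = 0.122), each from 100000 resamples, where a trade would give values below 0.

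Lists not described so far did not pass. In females the medians were 0.27 for smooth muscle (camera adjusted p = 0.768), 0.03 for mitochondrially encoded genes (0.996), -0.08 for glycolysis (0.768), 0.10 for cholesterol synthesis (0.239), -0.03 for hypoxia (0.949), 0.38 for interferon response (0.239), 0.10 for the inflammatory and senescence secretome (0.579), 0.08 for BMP and TGF-beta (0.933), 0.14 for osteoclast regulators (0.768), 0.11 for immediate early (0.175) and 0.01 for ribosomal genes (0.949). In males they were -0.01 for osteoclast (0.812), 0.99 for granulocyte and mast cell (0.812), 0.01 for oxidative phosphorylation (0.912), -0.11 for mitochondrially encoded genes (0.126), -0.08 for the tricarboxylic acid cycle (0.245), -0.05 for cholesterol synthesis (0.245), 0.06 for hypoxia (0.912), 0.16 for interferon response (0.396), 0.21 for the secretome (0.933) and -0.12 for immediate early genes (0.912). The male granulocyte and interferon lists had positive medians while camera pointed down, the male oxidative phosphorylation median and camera also differed in sign, and so did the male hypoxia median (0.06) and mean (-0.08). For the difference between sexes, lymphocyte (-0.65, 0.446) and endothelial genes (0.89, 0.533) did not pass.

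For the 255 genes between the sexes on control diet the real split was the only 1 of 35 with as many, and the highest other gave 1. Xist and the Y-linked genes alone put the real split above that. The splits therefore do not decide whether chance accounts for the other genes. For the difference between sexes 0 genes passed (edgeR, 960 at an unadjusted p under 0.05, 26 by DESeq2, 0 by limma-voom). A count of 0 is met by all 60 splits whatever the data, so these say nothing about chance, and the highest other gave 1.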
